A study of Mus musculus with 24 samples.

How the data were processed

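RNA of 24 samples was measured on Illumina bead arrays with 45281 probes. Per the labels, the 8 groups had 3 replicates each, and each mucosal replicate pooled several adult mice. OM came from F1 hybrid mice, Sox2GBC and Sus from a Sox2-GFP line and the 2 Neurog1 groups from a Neurog1-GFP line, both crossed to FVB/NJ, and the OMP groups from an OMP-GFP line crossed to CD-1. Mouse line is thus tied to cell stage in most comparisons. Cells were sorted live, RNA was isolated by column and labelled as biotinylated cRNA, per the labels' protocols. The mREF arrays are technical repeats of a commercial reference RNA.

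The deposited table without normalization holds bead intensity values from GenomeStudio, whose version is not given in the sources used here, and a detection p-value for each probe and array. Negative values show that background had been subtracted from these deposited intensity values. The deposited series matrix holds linear intensity values from the authors whose column medians lie between 120.7 and 121, with a minimum of 74.87, so they had been brought to a common distribution, and they rank probes as the first table does. 1 column of the OMP group carries replicate number 4 and was taken as its replicate 3. No per-sample column was left unmatched.

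A gene symbol was assigned to 34885 probes (77.0%), 18 probes carry several, and 10378 (22.9%) have no gene in the annotation used here and were left out. Mean signal per array ran from 215 to 722 intensity units, median signal from 5.79 to 21.5, the ratio of signal to noise from 30.3 to 86.1, and 33.9% to 48.3% of probes were detected. Detection p-values imply 936 negative control beads.

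Background was corrected from the detection p-values with the normexp method of limma 3.58.1 in R 4.3.3, an offset of 16 was added, and arrays were quantile normalized and put on a log2 scale. Probes detected at p under 0.01 on at least 3 arrays were kept, and each gene was read by its brightest probe. Probes of 1 gene can disagree, and for a called named gene 1 or more other probes' values are given where any had the opposite sign or less than 0.5 of the size. This left 11870 genes on the 21 arrays of the mucosa and 12495 on all 24, the latter used for OM against mREF only. Of 1071 named odorant receptor genes, 580 were tested, and they are treated as a family.

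Groups were compared with linear models and moderated t statistics in limma, with 14 residual degrees of freedom and 18.92 in all after moderation. All adjusted p are Benjamini-Hochberg values from limma, and genes under 0.05 are called. Where the lower group was not detected on any array, the difference is also given as a lower bound, written as at least N-fold. The bulbectomy interaction was a contrast of the 2 lesion effects. Fixed gene lists, 27 in number, were tested with camera at a preset correlation between genes of 0.01, then with an estimated correlation and with fry, if they held at least 5 measured members. Each list is also counted with p adjusted over the list alone. Over 11 comparisons 286 list tests were made, of which 150 passed at the preset correlation and 158 with fry.

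Named genes followed a rule fixed with the comparisons, lists and most alternatives before the data were examined. The reporter genes Sox2, Neurog1 and Omp are given for each group, as a range where groups are alike. From each of the 5 main comparisons up to 8 genes with the largest rise and 8 with the largest fall could be named, and up to 4 each way elsewhere. These had to be called, have arrays that did not overlap between the groups, be detected on all 3 arrays of the higher group and carry no clone name. Values of 3 arrays against 3 do not overlap by chance for 10% of genes. From each list discussed, up to 4 called members and up to 2 others were eligible.

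The fit was tested on simulated data for OMP-OBX against OMP, with 11870 genes and 50 changed genes of each size. Changes of 0.5, 1, 2 and 3 log2 units were recovered for 2%, 46%, 96% and 98% of them, none with the wrong sign, with 9 false calls among 130. In the simulated unchanged comparison limma called 0 genes.

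Alternatives were no background correction (offset 64.22), cyclic loess, scaling by medians alone, the authors' processed values, no filter and a stricter filter, the mean of all probes, fits with the compared groups only, array weights, the replicate number as a block and leaving out each array in turn. After the spread of the negative controls was seen, arrays were put into 4 noise classes with ranges of 4.31 to 4.87, 5.97 to 7.28, 10.0 to 11.2 and 15.1 to 21.99, and a block on that class and a fit without the lowest class were added. Whether replicate numbers pair the samples was checked from correlations of deviations from the group means. Among compared groups of the mucosa only OM and OMP had every correlation over 0.1 (0.60, 0.18 and 0.28), and replicate 1 of both lies in the lowest noise class. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.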

Results

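Messenger RNA was measured with Illumina bead arrays in cells of the adult mouse olfactory mucosa, in 8 groups of 3 arrays each. Each mucosal replicate pooled cells of several mice. The whole dissociated mucosa, sorted for live cells, is called OM. Sorted populations, named after their labels, were globose basal cells, the neurogenic progenitors of the epithelium (Sox2GBC, low Sox2-GFP), precursors and young neurons carrying a Neurog1-GFP reporter (Neurog1-Ctrl), mature neurons carrying a GFP reporter at the Omp gene (OMP) and sustentacular cells, the supporting cells of the epithelium (Sus, high Sox2-GFP). In the Neurog1-OBX and OMP-OBX groups the same reporters were sorted 3 weeks after removal of 1 olfactory bulb, the target of the neurons, from the side of the lesion. A commercial mouse reference RNA (mREF) was run as technical repeats.

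Between 33.9% and 48.3% of the 45281 probes were detected per array, and replicates of a group correlated with r of 0.942 to 0.991 across genes, which are not independent replicates. The spread of the negative controls ran from 4.31 to 21.99 intensity units and fell into 4 classes of arrays. Most groups were spread over several classes, but the 3 OMP-OBX arrays lay in class 3 and the 3 Neurog1-Ctrl arrays in class 4. Counts with that class as a block are given beside the main counts. Within a single class, 99.5% to 100% of called genes kept their direction, although the same arrays enter the pooled fit. For OMP-OBX against OMP only OMP replicate 3 shared the class, so that share rests on 1 OMP array, and with the class as a block that array has a weight of -0.682 against -0.333 without. Log2 differences are followed by their standard error, with 3 arrays per group, and the small number of arrays limits the precision.

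The reporter genes checked the labels first. Neurog1, a proneural transcription factor, was detected on all 3 arrays of Neurog1-Ctrl (mean log2 6.60 ± 0.49 SD) and of Neurog1-OBX (6.27 ± 0.39 SD), and on 0 arrays of every other group (means of 4.86 to 5.63). Sox2, a progenitor and supporting cell transcription factor, was highest in Sus (9.73 ± 0.23 SD, n = 3) and lower in Sox2GBC (6.23 ± 0.97 SD, detected on 2 of 3 arrays), against 8.40 ± 0.21 SD in OM, 6.16 ± 0.11 SD in Neurog1-Ctrl, 6.93 ± 0.38 SD in Neurog1-OBX, 6.92 ± 0.20 SD in OMP, 6.53 ± 0.23 SD in OMP-OBX and 5.09 ± 0.42 SD in mREF. Sox2 thus sets Sus apart but does not set Sox2GBC above the neuronal sorts, and a second Sox2 probe was detected on 0 of 3 Sox2GBC arrays and on 3 of 3 Sus arrays. Omp, which marks mature olfactory neurons, lay between 15.2 and 15.5 in all groups of the mucosa except Sus (13.95 ± 0.24 SD), close to the top of the scale. A dimmer Omp probe gave 7.45 ± 0.90 SD in Sox2GBC, 10.4 ± 0.52 SD in Neurog1-Ctrl and 9.89 ± 0.82 SD in OMP. It was detected on 3 of 3 arrays of Sox2GBC and of Sus (6.71 ± 0.06 SD), so whether the Omp signal in these sorts comes from the sorted cells or from RNA of neurons carried along was not resolved. In mREF the brighter probe read 5.47 ± 0.37 SD.

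**Figure D1:**
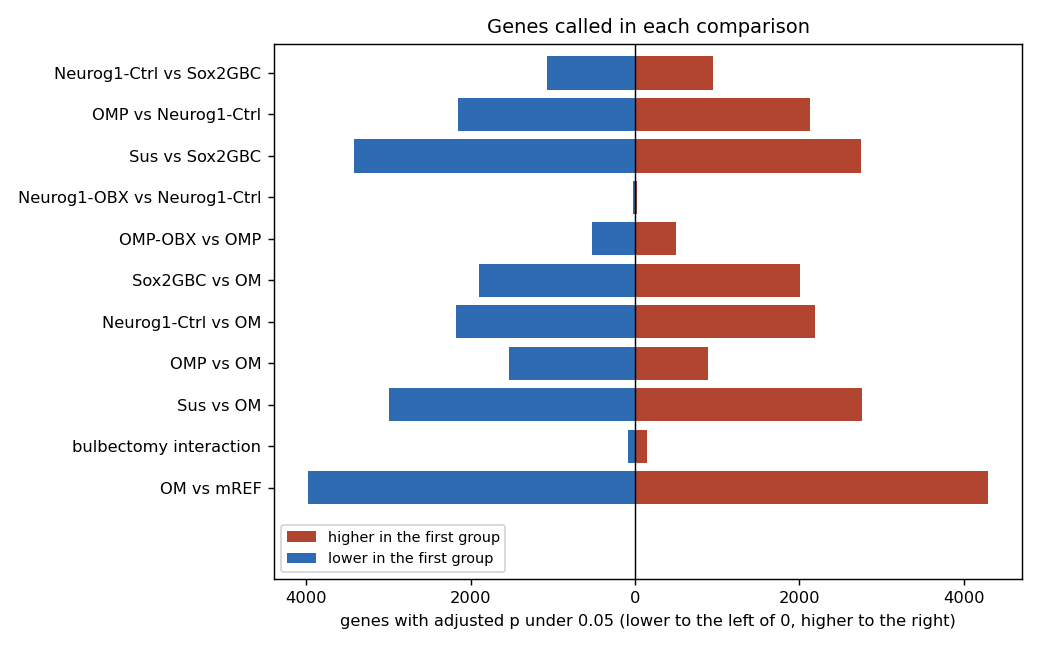
Genes past an adjusted p of 0.05 in each comparison, as bars of the number of genes higher and lower in the first group named. The fewest genes, 45, were called between Neurog1-OBX and Neurog1-Ctrl, and the most, 8277, between OM and mREF.

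Neurog1-Ctrl against Sox2GBC compares the sorts that the labels name for neuronal precursors and for globose basal cells. Sox2, the gene of the Sox2GBC reporter, averaged 6.16 and 6.23, and Gap43 of young neurons 12.96 and 12.65, without passing, so these genes do not set Sox2GBC apart as an earlier stage. Neurog1 itself was higher in Neurog1-Ctrl (0.97 ± 0.25, adjusted p = 0.0121, at least 1.47-fold), a call that ended without Sox2GBC replicate 1 (0.87, adjusted p = 0.0542), without Neurog1-Ctrl replicate 1 (0.69, adjusted p = 0.0936) and with median scaling (0.75, adjusted p = 0.123). The chemokine gene Cxcl14 was higher (3.02 ± 0.30, adjusted p = 6.53e-06, at least 5.43-fold), as were the adhesion gene Kirrel3 (1.79 ± 0.27, adjusted p = 0.000243) and Cplx2, which controls vesicle release (1.90 ± 0.31, adjusted p = 0.000451). Lower in Neurog1-Ctrl were the ionocyte factor Ascl3 (-3.73 ± 0.56, adjusted p = 0.000218), the Notch target Hes1 (-1.73 ± 0.33, adjusted p = 0.00151) and the gland factor Sox9 (-2.34 ± 0.29, adjusted p = 3.92e-05). Omp did not pass on the probe used (-0.05 ± 0.18, adjusted p = 0.901) and read 2.97 on its dimmer probe, and the precursor factor Insm1 did not pass (0.41 ± 0.40, adjusted p = 0.555).

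Of 11870 genes tested, 2019 differed, 947 higher and 1072 lower in Neurog1-Ctrl, and 1333 of them by at least 2-fold. With the noise class as a block 2022 were called. The count was 1165 without Neurog1-Ctrl replicate 1 and 1192 without Neurog1-Ctrl replicate 3. Cyclic loess split the calls into 741 higher and 1350 lower (35.4% higher against 46.9%), and median scaling into 782 and 1338 (36.9% higher).

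Among the largest rises were Gdpd3, a lysophospholipase D gene (4.61), Nqo1, a quinone reductase gene (2.75), Slc4a4, a bicarbonate transporter gene (2.52), and Muc13, a membrane mucin gene (2.48, other probe 1.09). Adgrb3, an adhesion receptor gene, differed by 3.12 on the probe used and by -0.06 and 2.22 on its other probes. Among the largest falls were those of Pdrg1 (-5.87), Cops8 (-5.07, at least 16.4-fold lower), the kinase gene Tesk1 (-5.05, at least 23.2-fold lower) and the flagellar gene Cfap69 (-4.61, at least 18.9-fold lower). Tesk1 and Cfap69 were also lower on every array of the Neurog1-GFP line, lesioned or not, than on all other arrays of the mucosa. Dennd1c fell by 4.92 on the probe used, while its other probe differed by 0.48. Ces1a, a carboxylesterase gene (-4.36, at least 9.23-fold lower), and the secretory genes Dcpp2 (-4.19, at least 8.52-fold lower) and Dcpp3 (-4.24, at least 7.77-fold lower) were lower as well.

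Lists of mature neurons, odorant receptors and presynaptic genes were shifted upwards in Neurog1-Ctrl, and lists of immature neurons, precursors and mitosis did not pass. The 22 mature olfactory sensory neuron genes measured held 8 higher, 0 lower and 14 that did not pass, with 11 higher and 0 lower adjusted over the list alone (camera adjusted p = 2.35e-05, adjusted p = 0.148 with an estimated correlation). Faim2, a death receptor inhibitor gene, was higher (1.24 ± 0.20, adjusted p = 0.000319), as was the glutamate transporter gene Slc17a6 (0.83 ± 0.19, adjusted p = 0.00533), while Gng13 did not pass (0.47). Among 580 odorant receptors, 169 were higher and 3 lower while 408 did not pass, with 220 higher and 4 lower adjusted over the list alone (camera adjusted p = 8.61e-22, adjusted p = 0.133 with an estimated correlation). Of 14 measured presynaptic genes, 5 were higher, 0 were lower and 9 did not pass, with 6 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.000834, adjusted p = 0.132 with an estimated correlation). Sv2a, a synaptic vesicle gene, was among the latter (0.84 ± 0.18, adjusted p = 0.00289). The 19 immature olfactory sensory neuron genes measured held 1 higher, 0 lower and 18 that did not pass, with 1 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.837, adjusted p = 0.937 with an estimated correlation). For that list the mean was 0.05, the median -0.00 and the camera direction upwards; Stmn2 read 0.17 and Ncam1 0.36. Among 12 immediate neuronal precursor genes, 1 was higher and 0 lower while 11 did not pass, with 1 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.691, adjusted p = 0.929 with an estimated correlation). Neurog1 was the member that passed, and Sox11 read -0.22. Of 16 measured G2/M and mitosis genes, 0 were higher, 0 were lower and 16 did not pass, with 0 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.157, adjusted p = 0.794 with an estimated correlation). Prc1 (0.33) and Cenpa (0.29), both mitotic genes, did not pass.

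Lists of other epithelial cell types and of progenitors shifted downwards. The 15 sustentacular cell genes measured held 0 higher, 11 lower and 4 that did not pass, with 1 higher and 11 lower adjusted over the list alone (camera adjusted p = 4.05e-07, adjusted p = 0.133 with an estimated correlation). The keratin genes Krt18 (-2.51) and Krt8 (-2.23) were lower. Among 24 xenobiotic metabolism genes, 1 was higher and 19 lower while 4 did not pass, with 2 higher and 20 lower adjusted over the list alone (camera adjusted p = 7.59e-10, adjusted p = 0.132 with an estimated correlation). Gstm2, a glutathione transferase gene (-2.03), and Fmo1, a monooxygenase gene (-2.09, other probe -0.08), passed. Of 11 measured horizontal basal cell genes, 0 were higher, 6 were lower and 5 did not pass, with 0 higher and 9 lower adjusted over the list alone (camera adjusted p = 1.05e-05, adjusted p = 0.132 with an estimated correlation). These held Krt5 (-1.66) and Krt14 (-1.79), the keratins of horizontal basal cells, and the integrin gene Itgb4 (-1.77). The 11 Bowman gland genes measured held 0 higher, 6 lower and 5 that did not pass, with 0 higher and 7 lower adjusted over the list alone (camera adjusted p = 4.6e-06, adjusted p = 0.132 with an estimated correlation). The water channel gene Aqp5 was lower (-2.33), as was lactotransferrin, Ltf (-3.08, other probe -1.51), and Obp2a did not pass (-1.38 ± 2.02). Among 11 microvillar and brush cell genes, 0 were higher and 7 lower while 4 did not pass, with 0 higher and 7 lower adjusted over the list alone (camera adjusted p = 3.75e-05, adjusted p = 0.133 with an estimated correlation). Trpm5, the cation channel gene of brush cells, was lower (-1.52), with Avil (-1.98). Of 13 measured immediate early genes, 0 were higher, 8 were lower and 5 did not pass, with 0 higher and 8 lower adjusted over the list alone (camera adjusted p = 1.37e-06, adjusted p = 0.132 with an estimated correlation). Zfp36 (-2.96), Ier3 (-2.65), Fos (-2.45) and Junb (-1.89), all induced rapidly by stimulation, were lower. The 9 globose basal cell and progenitor regulators measured held 1 higher, 3 lower and 5 that did not pass, with 1 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.0187, adjusted p = 0.342 with an estimated correlation).

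OMP against Neurog1-Ctrl compares the sorts that the labels name for mature neurons and for precursors. Adcy3, the adenylyl cyclase of odorant transduction, was higher in OMP (2.38 ± 0.27, adjusted p = 2.39e-06, other probe 0.99), as was Ano2, its chloride channel (1.87 ± 0.20, adjusted p = 1.07e-06). The growth cone gene Gng8 (-4.72 ± 0.41, adjusted p = 1.43e-07), the intermediate filament gene Vim (-4.50 ± 0.50, adjusted p = 1.86e-06) and the precursor factors Insm1 (-3.02 ± 0.40, adjusted p = 1.26e-05) and Sox11 (-3.41 ± 0.35, adjusted p = 7.03e-07, least changed of 3 other probes -1.34) were lower. Omp itself, near the top of the scale, did not pass (0.04 ± 0.18, adjusted p = 0.871).

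Here 4279 of 11870 genes differed, 2128 higher and 2151 lower in OMP, with 2383 changed by at least 2-fold. The noise class as a block gave 3832. Cyclic loess split the calls into 2790 higher and 1830 lower (60.4% higher against 49.7%) and moved the median of all genes by 0.12. Among the largest rises were Cfap69 (6.98, at least 98.1-fold), Tesk1 (4.99, at least 22.2-fold), Cops8 (4.72, at least 12.9-fold), Pdrg1 (5.21) and the microtubule binding gene Clip4 (4.71). Fgfr1op2 rose by 4.55 on the probe used and read 0.35 on its other probe. Cfap69, Tesk1 and Fgfr1op2 were low on every Neurog1-GFP array, lesioned or not. Line and cell stage cannot be told apart for any gene here. Tesk1 averaged 10.48 in Sox2GBC, 5.43 in Neurog1-Ctrl and 10.41 in OMP. Among the largest falls were the collagen gene Col9a2 (-5.21), Gdpd3 (-4.69), the gastrin releasing peptide gene Grp (-4.43), Ooep (-4.30) and the long noncoding RNA Miat (-4.32, other probe -0.98). Cxcl14, higher in Neurog1-Ctrl than in Sox2GBC, was lower in OMP (-3.61).

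Lists of neuronal function rose from Neurog1-Ctrl to OMP, and so did lists of horizontal basal and sustentacular cells, which are not neurons. Among 22 mature olfactory sensory neuron genes, 16 were higher and 0 lower while 6 did not pass, with 18 higher and 0 lower adjusted over the list alone (camera adjusted p = 1.17e-07, adjusted p = 0.136 with an estimated correlation). Umodl1 was higher (2.75). Cngb1, a subunit of the olfactory channel, was 2.07 higher on the probe used and read -0.73 on its other probe. Of 580 measured odorant receptors, 273 were higher, 33 were lower and 274 did not pass, with 288 higher and 33 lower adjusted over the list alone (camera adjusted p = 5.54e-12, adjusted p = 0.43 with an estimated correlation). The 21 olfactory cilia genes measured held 8 higher, 0 lower and 13 that did not pass, with 8 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.00676, adjusted p = 0.122 with an estimated correlation). The ciliary motor gene Kif17 (2.28, at least 3.38-fold, other probe 0.62) and the transport genes Ift122 (1.34) and Bbs1 (0.83) were higher, and Ift20 read 0.03. Among 14 presynaptic genes, 9 were higher and 0 lower while 5 did not pass, with 11 higher and 0 lower adjusted over the list alone (camera adjusted p = 5.43e-05, adjusted p = 0.122 with an estimated correlation). Sv2b (1.76), Slc17a6 (1.46) and the calcium sensor gene Syt1 (1.31) were higher. Of 11 measured horizontal basal cell genes, 8 were higher, 0 were lower and 3 did not pass, with 8 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.00112, adjusted p = 0.197 with an estimated correlation). Krt5 (1.88), Trp63, the basal cell factor (1.52), and Itgb4 (1.51) were higher. The 15 sustentacular cell genes measured held 6 higher, 0 lower and 9 that did not pass, with 9 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.00322, adjusted p = 0.456 with an estimated correlation). Among these Cyp2a5, a cytochrome P450 gene, did not pass (0.37).

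Lists of immature and dividing cells fell. Among 19 immature olfactory sensory neuron genes, 0 were higher and 15 lower while 4 did not pass, with 0 higher and 16 lower adjusted over the list alone (camera adjusted p = 1.24e-09, adjusted p = 0.122 with an estimated correlation). Cxcr4, the chemokine receptor gene of migrating cells (-3.76), Marcksl1 (-3.28) and Marcks (-2.61), which act at the growing cell edge, were lower. Of 12 measured immediate neuronal precursor genes, 0 were higher, 10 were lower and 2 did not pass, with 0 higher and 10 lower adjusted over the list alone (camera adjusted p = 8.15e-07, adjusted p = 0.122 with an estimated correlation). Mfng, a modifier of Notch receptors (-4.27), and Hes6 (-2.40) were lower. The 16 G2/M and mitosis genes measured held 0 higher, 14 lower and 2 that did not pass, with 0 higher and 14 lower adjusted over the list alone (camera adjusted p = 8.15e-07, adjusted p = 0.43 with an estimated correlation). Cdca8 (-3.06), Birc5 (-2.90) and Cenpa (-2.55), all of the mitotic chromosome, were lower. Among 17 G1/S and DNA replication genes, 0 were higher and 10 lower while 7 did not pass, with 0 higher and 12 lower adjusted over the list alone (camera adjusted p = 0.000571, adjusted p = 0.456 with an estimated correlation). Mcm2, a replicative helicase gene (-2.02), and Tyms, which makes thymidylate (-1.45, other probes -1.18 and -0.13), were lower. Of 15 measured chromatin regulators, 1 was higher, 8 were lower and 6 did not pass, with 1 higher and 8 lower adjusted over the list alone (camera adjusted p = 0.0102, adjusted p = 0.43 with an estimated correlation). Hmgb2 (-2.17) and Cbx2 (-1.62) were lower. Smarcc1, a remodeller subunit gene, rose by 2.76 and Hdac2, a deacetylase gene, fell by 1.83 on the probes used, while their other probes read 0.21 and 0.30.

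**Figure D2:**
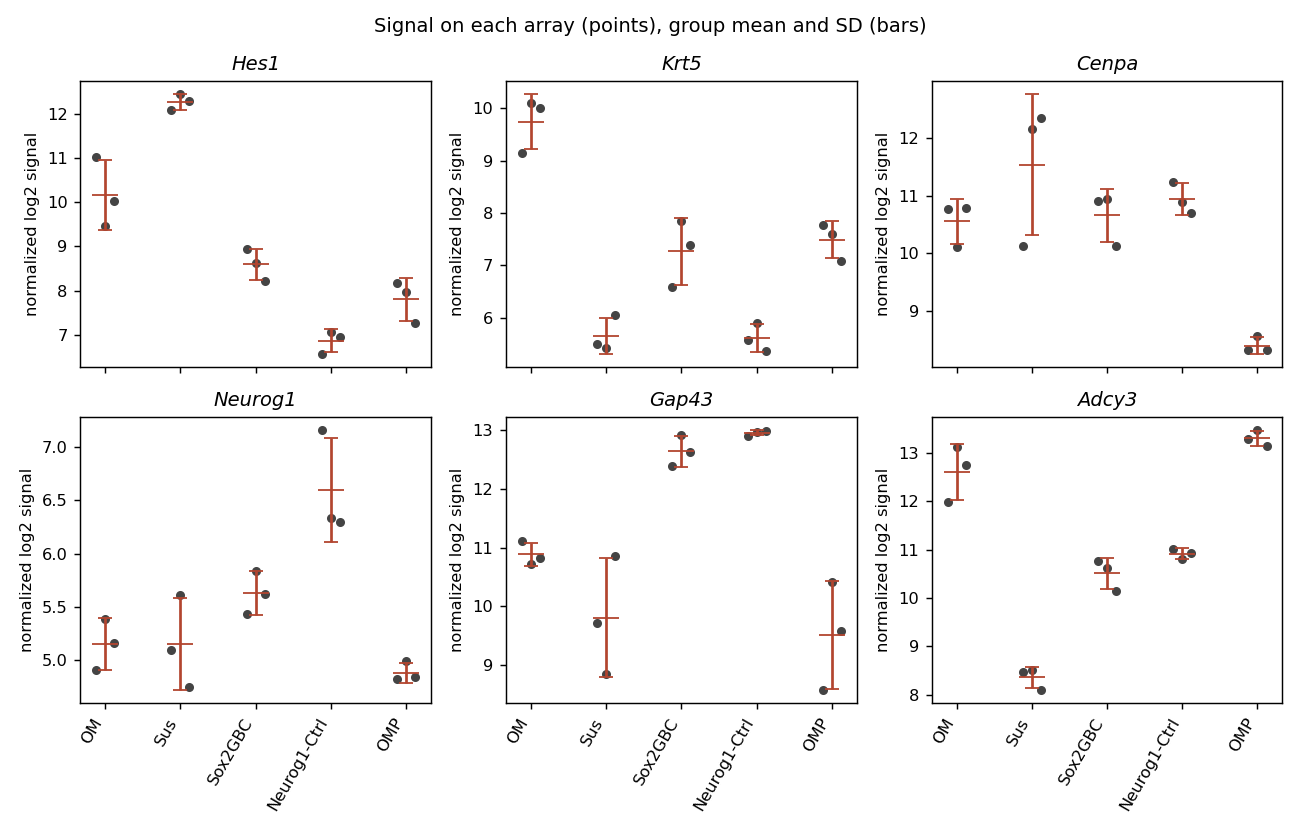
Normalized log2 signal (vertical axis) of 6 genes on each array (points) of OM and the unlesioned sorted groups, with bars for the group mean and SD. Gap43 averaged 12.65 in Sox2GBC, 12.96 in Neurog1-Ctrl and 9.52 in OMP.

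Genes with opposite changes at the 2 steps were counted next. The numbers were 159 genes highest in Neurog1-Ctrl and 343 lowest there, against 171.6 and 192.2 for independent lists, and 267 rose and 97 fell at both steps, against 169.8 and 194.3. Both steps use the same 3 Neurog1-Ctrl arrays, which are too few to divide, so part of the number lowest there may come from these shared arrays, and the number highest there was below that of independent lists. The number lowest there was 163 without Neurog1-Ctrl replicate 1, 229 without Neurog1-Ctrl replicate 3, 542 with cyclic loess and 248 on the authors' values, and the number for independent lists was not computed again for these. In 20 simulations of unchanged groups the mean was 0 genes highest and 0.05 lowest. Cxcl14 (3.02, then -3.61), Gdpd3 (4.61, then -4.69), the amino acid transporter gene Slc38a1 (1.79, then -2.04), the transcription factor genes Cebpa (1.69, then -1.84) and Olig2 (1.62, then -1.73) and the axon guidance gene Sema6d (1.55, then -1.78) were highest in Neurog1-Ctrl. The number highest there was 105 without Sox2GBC replicate 3, 70 without Neurog1-Ctrl replicate 1 and 82 without Neurog1-Ctrl replicate 3.

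Sus against Sox2GBC compares the cells of the same mouse line with high and with low Sox2-GFP. Sox2 itself was higher in Sus (3.50 ± 0.33, adjusted p = 9.41e-08), with Hes1 (3.68 ± 0.33, adjusted p = 7.78e-08) and the Wnt receptor gene Lgr5 (3.53 ± 0.37, adjusted p = 3.1e-07). Ugt2a1, which conjugates odorants (4.02 ± 0.66, adjusted p = 4.41e-05), and the P450 gene Cyp2b10 (3.62 ± 0.32, adjusted p = 7.05e-08, other probe 1.38) were higher. Dcx, of migrating young neurons (-3.68 ± 0.34, adjusted p = 8.64e-08), and the synaptic vesicle gene Syp (-2.58 ± 0.23, adjusted p = 7.46e-08) were lower.

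In this comparison 6167 of 11870 genes differed, 2744 higher and 3423 lower in Sus, 3962 of them by at least 2-fold, and 6256 with the noise class as a block. Median scaling moved the median of all genes by -0.13. Among the largest rises were Ccn1, of the matrix (4.85, at least 19.2-fold), the heat shock gene Hspa1b (4.10, at least 9.83-fold), Cyp2b23 (4.08), Tmod1 (3.97) and the stress factor genes Fosb (3.99) and Atf3 (3.92). Atp6v1b1, a proton pump gene, rose by 4.05 on the probe used and read 0.45 on its other probe. The largest falls among calls that held without each array in turn were those of the secretory gene Bpifb6 (-5.66), the smooth muscle actin gene Acta2 (-4.47, at least 17-fold lower, other probes -0.94, -0.77 and -2.34), Scgb2b27 (-4.39, at least 9.71-fold lower), Bpifb3 (-4.30) and the endothelial claudin gene Cldn5 (-4.26).

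Lists higher in Sus were these. The 15 sustentacular cell genes measured held 10 higher, 1 lower and 4 that did not pass, with 10 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.000623, adjusted p = 0.391 with an estimated correlation). Epas1, the hypoxia factor gene (3.50), and Krt18 (2.17) were higher, and Sec14l3 read 0.32 on the probe used and 3.18 and 2.20 on its others. The sulfotransferase gene Sult1d1 was lower on the probe used (-2.52), with 0.05 on its other probe. Among 24 xenobiotic metabolism genes, 18 were higher and 1 lower while 5 did not pass, with 19 higher and 1 lower adjusted over the list alone (camera adjusted p = 3.15e-05, adjusted p = 0.33 with an estimated correlation). Fmo1 (2.88) and the epoxide hydrolase gene Ephx1 (2.26) were higher. Of 9 measured globose basal cell and progenitor regulators, 6 were higher, 0 were lower and 3 did not pass, with 6 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.00564, adjusted p = 0.33 with an estimated correlation). The 12 Notch pathway genes measured held 6 higher, 1 lower and 5 that did not pass, with 6 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0274, adjusted p = 0.391 with an estimated correlation). Notch3 (2.88) and the Notch targets Hey1 (2.48) and Nrarp (1.39) were higher. Among 13 immediate early genes, 11 were higher and 0 lower while 2 did not pass, with 11 higher and 0 lower adjusted over the list alone (camera adjusted p = 3.36e-07, adjusted p = 0.13 with an estimated correlation). Junb (3.81), Zfp36 (3.55) and Ier2 (3.59, at least 4.73-fold) were higher. Of 16 measured G2/M and mitosis genes, 11 were higher, 0 were lower and 5 did not pass, with 11 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.00546, adjusted p = 0.572 with an estimated correlation). Aurkb (1.88) and Cdk1 (1.86), kinases of mitosis, were higher, although their arrays overlapped between the groups. Sus replicate 1 stood apart here, with Cenpa at 10.13 against 12.15 and 12.34 on the other Sus arrays.

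Neuronal, ciliary and endothelial lists were lower in Sus. The 22 mature olfactory sensory neuron genes measured held 1 higher, 18 lower and 3 that did not pass, with 1 higher and 18 lower adjusted over the list alone (camera adjusted p = 6.19e-07, adjusted p = 0.171 with an estimated correlation). Faim2 (-2.58, other probe -0.18) was lower, as were Rtp1 (-2.25) and Rtp2 (-2.88, other probe -0.59), which carry odorant receptors to the surface. Among 580 odorant receptors, 1 was higher and 224 lower while 355 did not pass, with 1 higher and 195 lower adjusted over the list alone (camera adjusted p = 7.28e-07, adjusted p = 0.511 with an estimated correlation). Of 19 measured immature olfactory sensory neuron genes, 0 were higher, 17 were lower and 2 did not pass, with 0 higher and 18 lower adjusted over the list alone (camera adjusted p = 6.19e-07, adjusted p = 0.171 with an estimated correlation). Stmn3 (-3.58), Crmp1 (-3.37) and Dpysl5 (-3.27), of axon growth, were lower. The 14 presynaptic genes measured held 0 higher, 11 lower and 3 that did not pass, with 0 higher and 12 lower adjusted over the list alone (camera adjusted p = 1.42e-05, adjusted p = 0.0989 with an estimated correlation). Syt1 (-2.59, other probes 0.03 and -1.81) and the fusion factor gene Napa (-1.70, other probes 1.52 and -1.30) were lower on the probes used. Among 21 olfactory cilia genes, 0 were higher and 17 lower while 4 did not pass, with 0 higher and 17 lower adjusted over the list alone (camera adjusted p = 0.000126, adjusted p = 0.0567 with an estimated correlation). Ift122 (-1.89) and Bbs7 (-1.72) were lower. Of 7 measured endothelial genes, 0 were higher, 7 were lower and 0 did not pass, with 0 higher and 7 lower adjusted over the list alone (camera adjusted p = 0.0142, adjusted p = 0.451 with an estimated correlation). Pecam1 (-1.62) and Esam (-2.92), of endothelial junctions, were lower. The 8 motile ciliated cell genes measured held 0 higher, 7 lower and 1 that did not pass, with 0 higher and 7 lower adjusted over the list alone (camera adjusted p = 0.0145, adjusted p = 0.193 with an estimated correlation). Ccdc39 (-1.95) and Rsph1 (-1.59), of motile cilia, were lower.

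Neurog1-OBX against Neurog1-Ctrl addresses how precursors change after the target is lost. The chitinase-like gene Chil3 was higher after bulbectomy (5.85 ± 0.56, adjusted p = 2.88e-05, at least 26.8-fold, other probes 2.79 and 2.55), and so was Chil4 (7.42 ± 1.20, adjusted p = 0.00903, at a mean of 14.82 after the lesion, near the top of the scale), whose call ended without Neurog1-Ctrl replicate 1 (6.56, adjusted p = 0.0868) and without Neurog1-OBX replicate 3 (7.27, adjusted p = 0.0531). Alox12e, an epidermal lipoxygenase gene (3.39 ± 0.44, adjusted p = 0.000763), and the immediate early gene Junb (1.98 ± 0.23, adjusted p = 0.000227) were higher. The survival gene Bcl2 was lower (-2.16 ± 0.25, adjusted p = 0.000227, least changed of 4 other probes -0.65). Smarcc1 was higher on the probe used (2.48 ± 0.34, adjusted p = 0.00192), with 0.17 on its other probe, and the mean of both did not pass (adjusted p = 0.0765).

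Only 45 of 11870 genes differed, 22 higher and 23 lower, 41 by at least 2-fold, and 1222 had an unadjusted p under 0.05. The noise class as a block gave 94 genes. The count was 8 without Neurog1-Ctrl replicate 1, 20 without Neurog1-Ctrl replicate 2, 11 without Neurog1-Ctrl replicate 3, 18 without Neurog1-OBX replicate 1, 28 without Neurog1-OBX replicate 2 and 11 without Neurog1-OBX replicate 3, and 14 of 19 named calls ended without 1 array. Xist was detected on 0 of 3 Neurog1-OBX arrays and 2 of 3 Neurog1-Ctrl arrays, and the sex of the pooled mice was not a covariate. Median scaling split the calls into 34 higher and 19 lower (64.2% higher against 48.9%). Among the other large rises, the vasopressin gene Avp (3.31 ± 0.60, adjusted p = 0.0167) lost its call without Neurog1-Ctrl 1, 2 or 3 or Neurog1-OBX 1 or 2 (adjusted p of 0.0622 to 0.111). The matrix gene Ccn2 (2.37 ± 0.40, adjusted p = 0.0138) lost it without Neurog1-Ctrl 1 or 3 or Neurog1-OBX 3 (0.0581 to 0.111), and Fos (2.24 ± 0.39, adjusted p = 0.0138) without Neurog1-Ctrl 1 or 2 or Neurog1-OBX 3 (0.0663 to 0.111).

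Among 13 immediate early genes, 4 were higher and 0 lower while 9 did not pass, with 7 higher and 0 lower adjusted over the list alone (camera adjusted p = 5.79e-13, adjusted p = 0.064 with an estimated correlation). Dusp1 read 0.76 and Jun 0.12, without passing. Of 580 measured odorant receptors, 0 were higher, 11 were lower and 569 did not pass, with 0 higher and 42 lower adjusted over the list alone (camera adjusted p = 2.15e-16, adjusted p = 0.492 with an estimated correlation). The 22 mature olfactory sensory neuron genes measured held 0 higher, 0 lower and 22 that did not pass, with 0 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.00237, adjusted p = 0.519 with an estimated correlation). This list did not pass without Neurog1-OBX replicate 1 (adjusted p = 0.131). Omp read 0.23 on the probe used, near the top of the scale. Its dimmer probe went the other way, with 10.43 in Neurog1-Ctrl and 9.38 in Neurog1-OBX. Among 9 globose basal cell and progenitor regulators, 0 were higher and 0 lower while 9 did not pass, with 1 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.00224, adjusted p = 0.492 with an estimated correlation). Their mean was 0.53, and Sox4 read 0.92 (other probe -0.27). Of 11 measured Bowman gland genes, 0 were higher, 0 were lower and 11 did not pass, with 1 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.00224, adjusted p = 0.492 with an estimated correlation). Their mean was 0.99, with 1.77 for Ltf, and they did not pass without Neurog1-OBX replicate 1 (adjusted p = 0.0742). The 19 leukocyte genes measured held 0 higher, 0 lower and 19 that did not pass, with 0 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.0155, adjusted p = 0.519 with an estimated correlation). The lysozyme genes Lyz1 (0.51) and Lyz2 (0.41) did not pass, and the list's adjusted p was 0.0570 without Neurog1-Ctrl replicate 1 and 0.181 without Neurog1-OBX replicate 1.

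OMP-OBX against OMP addresses the same lesion in neurons that carry the Omp reporter. Gap43, the growth cone gene of young neurons (3.38 ± 0.40, adjusted p = 2.98e-05), and Stmn1, which frees tubulin (3.38 ± 0.49, adjusted p = 0.000178), were higher after bulbectomy. Chil3 (4.56 ± 0.56, adjusted p = 3.77e-05, at least 12.6-fold, other probes at most 2.24) and Chil4 (7.48 ± 1.20, adjusted p = 0.000401) were higher, with the interferon regulatory factor gene Irf5 (3.15 ± 0.29, adjusted p = 3.4e-06). Chil4 averaged 14.27 after the lesion, near the top of the scale. Cdh23, a cadherin gene, was lower (-2.59 ± 0.37, adjusted p = 0.000165). Omp did not pass on the probe used (-0.06 ± 0.18, adjusted p = 0.893), which lies near the top of the scale and may hide a change. Its dimmer probe averaged 9.89 in OMP and 9.47 in OMP-OBX.

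Here 1028 of 11870 genes differed, 504 higher and 524 lower, 645 by at least 2-fold, and 756 with the noise class as a block. The count was 651 without OMP replicate 1 and 654 without OMP-OBX replicate 1. Xist together with a gene of the Y chromosome was detected on 0 of 3 OMP arrays and 3 of 3 OMP-OBX arrays. The sex of the pooled mice was not a covariate. Median scaling split the calls into 534 higher and 326 lower (62.1% higher against 49.0%) and moved the median of all genes by 0.13. In the simulation of this comparison, changes of 0.5 log2 units were recovered for 1 of 50 genes, of 1 unit for 23, of 2 units for 48 and of 3 units for 49. Among the largest rises were also the angiogenin gene Ang4 (4.75), Avp (3.33) and Bean1 (3.12), and among the falls Mob3b (-2.35), Clip4 (-2.18), Lrrc18 (-2.11) and the trace amine receptor gene Taar2 (-2.17, at least 2.88-fold lower), whose call ended without OMP replicate 3 (-1.57, adjusted p = 0.0530). Arhgef25 differed by -2.32 on the probe used and 0.36 on its other probe.

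Among 19 immature olfactory sensory neuron genes, 7 were higher and 0 lower while 12 did not pass, with 12 higher and 0 lower adjusted over the list alone (camera adjusted p = 3.97e-09, adjusted p = 0.217 with an estimated correlation). Marcksl1 (2.13, least changed of 3 other probes 0.98) and Marcks (1.55) were higher. Of 580 measured odorant receptors, 19 were higher, 240 were lower and 321 did not pass, with 33 higher and 308 lower adjusted over the list alone (camera adjusted p = 3.46e-30, adjusted p = 0.217 with an estimated correlation). The 22 mature olfactory sensory neuron genes measured held 0 higher, 2 lower and 20 that did not pass, with 0 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.00399, adjusted p = 0.58 with an estimated correlation). This list did not pass with median scaling (adjusted p = 0.0537), nor did the call of Adcy3 (-1.26, adjusted p = 0.0765 there). Among 13 apoptosis genes, 3 were higher and 0 lower while 10 did not pass, with 3 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.0447, adjusted p = 0.217 with an estimated correlation). Apaf1, which activates caspases, was higher (0.93). This list did not pass with the noise class (adjusted p = 0.114) or the replicate number (adjusted p = 0.0513) as a block. Its adjusted p was 0.0575, 0.0567 and 0.0523 without OMP replicates 1, 2 and 3 and 0.0567 and 0.0700 without OMP-OBX replicates 2 and 3. Of 15 measured sustentacular cell genes, 0 were higher, 2 were lower and 13 did not pass, with 0 higher and 6 lower adjusted over the list alone (camera adjusted p = 0.000672, adjusted p = 0.58 with an estimated correlation). The 19 leukocyte genes measured held 1 higher, 0 lower and 18 that did not pass, with 1 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.431, adjusted p = 0.807 with an estimated correlation). Coro1a, an actin binding gene, was the member that passed (2.23), and Lyz2 read 0.19. Among 16 G2/M and mitosis genes, 0 were higher and 0 lower while 16 did not pass, with 0 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.611, adjusted p = 0.898 with an estimated correlation). Prc1 read 0.21 and Cenpa -0.13.

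**Figure D3:**
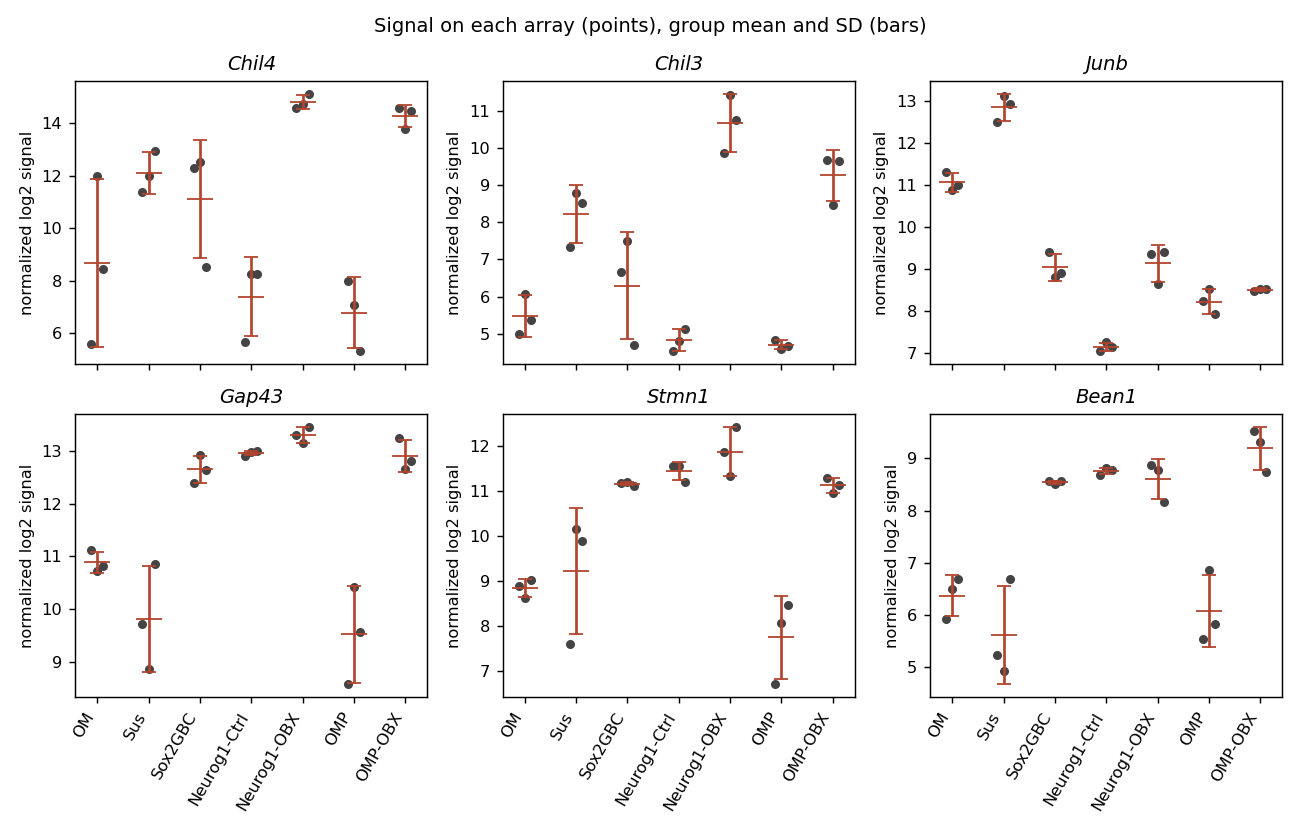
Normalized log2 signal (vertical axis) of 6 genes on each array (points) of the 7 groups of the mucosa, the lesioned ones included, with bars for the group mean and SD. Gap43 averaged 9.52 in OMP and 12.90 in OMP-OBX, and Junb 7.15 in Neurog1-Ctrl and 9.14 in Neurog1-OBX.

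Whether bulbectomy acted differently in the 2 populations was tested as an interaction, the OMP change minus the Neurog1 change. Gap43 (3.05 ± 0.57, adjusted p = 0.00947) and Marcksl1 (2.09 ± 0.39, adjusted p = 0.00933) rose more in OMP cells, and Bcl2 differed in the same direction on the probe used (1.78 ± 0.36, adjusted p = 0.013; other probes -0.41 to 1.93). Junb rose more in Neurog1 cells (-1.70 ± 0.32, adjusted p = 0.01). Its arrays overlapped between OMP-OBX and OMP but not between Neurog1-OBX and Neurog1-Ctrl. Prkd1, a kinase gene (-2.15 ± 0.36, adjusted p = 0.00549, other probes -0.57 and -0.82), was lower in the OMP change than in the Neurog1 change.

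The interaction passed for 234 of 11870 genes, 151 positive and 83 negative, 228 with at least 2-fold, and for 318 with the noise class as a block. The count was 108 without Neurog1-Ctrl replicate 1, 121 without 2 and 126 without 3, 142 without OMP replicate 1, 112 without Neurog1-OBX replicate 2 and 104 without 3, and 143, 122 and 123 without OMP-OBX replicates 1, 2 and 3. Cyclic loess split the calls into 135 positive and 145 negative (48.2% against 64.5%), and median scaling moved the median of all genes by 0.10. Of 19 measured immature olfactory sensory neuron genes, 5 were higher, 0 were lower and 14 did not pass, with 11 higher and 0 lower adjusted over the list alone (camera adjusted p = 6.87e-07, adjusted p = 0.404 with an estimated correlation). The 580 odorant receptors measured held 13 higher, 40 lower and 527 that did not pass, with 31 higher and 120 lower adjusted over the list alone (camera adjusted p = 1.94e-07, adjusted p = 0.682 with an estimated correlation). Among 13 immediate early genes, 0 were higher and 3 lower while 10 did not pass, with 1 higher and 5 lower adjusted over the list alone (camera adjusted p = 0.000676, adjusted p = 0.436 with an estimated correlation). Of 15 measured sustentacular cell genes, 0 were higher, 0 were lower and 15 did not pass, with 0 higher and 0 lower adjusted over the list alone (camera adjusted p = 5.69e-06, adjusted p = 0.436 with an estimated correlation). The 13 apoptosis genes measured held 3 higher, 0 lower and 10 that did not pass, with 5 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.0254, adjusted p = 0.307 with an estimated correlation). That list did not pass without Neurog1-OBX replicate 1 (adjusted p = 0.0803) or with the noise class as a block (adjusted p = 0.0644).

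Across 11870 genes, which are not independent replicates, the bulbectomy changes in the 2 populations correlated with Pearson 0.245 and Spearman 0.104 (jackknife SD 0.139 over arrays). With the noise class as a block they were 0.399 and 0.262, without OMP replicate 3 0.148 and 0.018, and without Neurog1-OBX replicate 1 0.159 and 0.028. The Spearman value was also 0.162 without OMP replicate 1 or without the low-noise arrays and 0.158 without Neurog1-OBX replicate 2. No p is given, and the 2 changes share no array.

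Each sorted population was set against OM, the tissue control, to show what sorting enriched. In Sox2GBC the receptor gene Ret (3.14 ± 0.22, adjusted p = 5.77e-08, at least 6.6-fold) and the collagen gene Col9a2 (3.79 ± 0.45, adjusted p = 7.32e-06) were higher than in OM. The antigen presentation gene H2-Ab1 (-4.88 ± 0.68, adjusted p = 3.36e-05) and the neutrophil gene S100a8 (-4.81 ± 0.57, adjusted p = 7.09e-06) were lower. Of 11870 genes, 3896 differed, 2004 higher and 1892 lower, 2104 by at least 2-fold, and 3723 with the noise class as a block. Median scaling gave 2185 higher and 1364 lower (61.6% higher against 51.4%) and moved the median of all genes by 0.14. Among 19 immature olfactory sensory neuron genes, 16 were higher and 0 lower while 3 did not pass, with 16 higher and 0 lower adjusted over the list alone (camera adjusted p = 6e-08, adjusted p = 0.109 with an estimated correlation). Dpysl5 (2.30) and Marcksl1 (1.99, least changed of 3 other probes 0.34) were higher. Of 22 measured mature olfactory sensory neuron genes, 0 were higher, 16 were lower and 6 did not pass, with 0 higher and 18 lower adjusted over the list alone (camera adjusted p = 9.31e-09, adjusted p = 0.109 with an estimated correlation). Umodl1 was lower (-2.68), and Rtp1 did not pass (-0.50). The 11 horizontal basal cell genes measured held 0 higher, 10 lower and 1 that did not pass, with 0 higher and 10 lower adjusted over the list alone (camera adjusted p = 3.2e-06, adjusted p = 0.109 with an estimated correlation). Krt5 was lower (-2.48). Among 19 leukocyte genes, 0 were higher and 18 lower while 1 did not pass, with 0 higher and 18 lower adjusted over the list alone (camera adjusted p = 3.26e-14, adjusted p = 0.109 with an estimated correlation). The complement gene C1qb was lower (-3.90).

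Neurog1-Ctrl against OM showed Cxcl14 (3.23 ± 0.30, adjusted p = 3.61e-07) and Glipr2 (3.28 ± 0.36, adjusted p = 1.69e-06) higher. The agouti gene, written a, was also higher (4.23 ± 0.58, adjusted p = 2.09e-05, other probe 2.01). H2-Eb1 (-6.45 ± 0.42, adjusted p = 7.34e-09, at least 34.6-fold lower), S100a8 (-6.33 ± 0.57, adjusted p = 3.23e-07, at least 45.6-fold lower) and Cfap69 (-6.35 ± 0.27, adjusted p = 2.04e-11, at least 63.2-fold lower) were lower. Cfap69 was low on every Neurog1-GFP array, and line and cell stage cannot be told apart for any gene here. There 4362 of 11870 genes differed, 2189 higher and 2173 lower, 2451 by at least 2-fold, and 4408 with the noise class as a block. Cyclic loess gave 1512 higher and 2745 lower (35.5% higher against 50.2%) and moved the median of all genes by -0.15. Of 19 measured immature olfactory sensory neuron genes, 17 were higher, 0 were lower and 2 did not pass, with 17 higher and 0 lower adjusted over the list alone (camera adjusted p = 8.42e-08, adjusted p = 0.109 with an estimated correlation). Dbn1 was higher (1.94). The 15 sustentacular cell genes measured held 0 higher, 13 lower and 2 that did not pass, with 0 higher and 13 lower adjusted over the list alone (camera adjusted p = 1.23e-07, adjusted p = 0.161 with an estimated correlation). Krt8 (-2.86) and Hes1 (-3.31) were lower. Among 11 horizontal basal cell genes, 0 were higher and 10 lower while 1 did not pass, with 0 higher and 10 lower adjusted over the list alone (camera adjusted p = 8.9e-10, adjusted p = 0.0339 with an estimated correlation). Krt14 was lower (-4.11). Of 19 measured leukocyte genes, 0 were higher, 18 were lower and 1 did not pass, with 0 higher and 18 lower adjusted over the list alone (camera adjusted p = 1.05e-15, adjusted p = 0.0393 with an estimated correlation). Csf1r, the macrophage growth factor receptor gene, was lower (-2.49, at least 2.98-fold lower).

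In OMP against OM, Me1, the malic enzyme gene (1.80 ± 0.35, adjusted p = 0.0014), and Dydc2 (2.69 ± 0.59, adjusted p = 0.00347) were higher. The chemokine gene Ccl4 (-4.61 ± 0.70, adjusted p = 0.000164) and Cd74, of antigen presentation (-4.24 ± 0.44, adjusted p = 5.47e-06), were lower. Omp, near the top of the scale on the probe used, did not pass (0.01 ± 0.18, adjusted p = 0.975). Of 11870 genes, 2431 differed, 892 higher and 1539 lower, 1407 by at least 2-fold, and 2412 with the noise class as a block. The count was 1435 without OMP replicate 3 (384 higher and 1051 lower) and 980 with the compared groups only (128 higher and 852 lower), so the higher calls were lost more often than the lower ones. The 22 mature olfactory sensory neuron genes measured held 7 higher, 0 lower and 15 that did not pass, with 10 higher and 0 lower adjusted over the list alone (camera adjusted p = 1.84e-05, adjusted p = 0.145 with an estimated correlation). Kirrel2 (1.10) and Faim2 (0.88) were higher. Among 580 odorant receptors, 207 were higher and 3 lower while 370 did not pass, with 298 higher and 3 lower adjusted over the list alone (camera adjusted p = 2.45e-24, adjusted p = 0.104 with an estimated correlation). Of 9 measured globose basal cell and progenitor regulators, 0 were higher, 8 were lower and 1 did not pass, with 0 higher and 8 lower adjusted over the list alone (camera adjusted p = 1.15e-06, adjusted p = 0.0718 with an estimated correlation). Hes1 (-2.37) and Sox9 (-1.87) were lower. The 19 leukocyte genes measured held 0 higher, 19 lower and 0 that did not pass, with 0 higher and 19 lower adjusted over the list alone (camera adjusted p = 5.05e-23, adjusted p = 0.0153 with an estimated correlation).

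Sus against OM showed Ppp1r27 (4.94 ± 0.23, adjusted p = 1.46e-11) and the flagellin receptor gene Tlr5 (3.70 ± 0.42, adjusted p = 6.5e-07) higher. Adh7, a retinol dehydrogenase gene (-6.04 ± 0.69, adjusted p = 8.79e-07, at least 31.5-fold lower), and the cytokine gene Il1b (-5.77 ± 0.59, adjusted p = 2.06e-07) were lower. Between these groups 5759 of 11870 genes differed, 2762 higher and 2997 lower, 3719 by at least 2-fold, and 5850 with the noise class as a block. Among 24 xenobiotic metabolism genes, 18 were higher and 4 lower while 2 did not pass, with 19 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.00127, adjusted p = 0.433 with an estimated correlation). Cyp2b10 (3.31, other probe 1.28) and Fmo2 (2.03) were higher. Of 16 measured G2/M and mitosis genes, 11 were higher, 0 were lower and 5 did not pass, with 14 higher and 0 lower adjusted over the list alone (camera adjusted p = 0.00209, adjusted p = 0.456 with an estimated correlation). Aurka was higher (1.25), and the arrays of Plk1 (2.01) overlapped between the groups. The 22 mature olfactory sensory neuron genes measured held 0 higher, 20 lower and 2 that did not pass, with 0 higher and 20 lower adjusted over the list alone (camera adjusted p = 4.43e-14, adjusted p = 0.0339 with an estimated correlation). Faim2 (-4.59) and Ano2 (-3.91) were lower. Among 19 leukocyte genes, 0 were higher and 18 lower while 1 did not pass, with 0 higher and 19 lower adjusted over the list alone (camera adjusted p = 4.18e-10, adjusted p = 0.0742 with an estimated correlation). C1qb was lower (-4.80, at least 13.1-fold lower).

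OM against mREF set the tissue against a mixed reference RNA whose 3 arrays repeat 1 sample, so on that side the adjusted p cover technical spread only. The secretoglobin gene Scgb1c1 (at least 762-fold), Cyp2a5 (at least 637-fold) and the potassium channel gene Kcnc4 (at least 588-fold) were higher in OM. These are given as bounds only, since their probes lie near the top of the scale in OM and were detected on 0 of 3 mREF arrays. Omp was higher in OM too, but no size is given, since its probe also lies near the top there and was detected on 1 of 3 mREF arrays. Gpnmb, a membrane glycoprotein gene (at least 221-fold lower, least changed of 3 other probes -3.08), Dlk1 (at least 147-fold lower) and the fibronectin gene Fn1 (-7.69 ± 0.32, adjusted p = 3.97e-15, least changed of 3 other probes -2.96) were lower. Of 12495 genes tested on all 24 arrays, 8277 differed, 4300 higher and 3977 lower, 5871 by at least 2-fold, and 8520 with the noise class as a block. Of 22 measured mature olfactory sensory neuron genes, 22 were higher, 0 were lower and 0 did not pass, with 22 higher and 0 lower adjusted over the list alone (camera adjusted p = 1.64e-15, adjusted p = 0.0153 with an estimated correlation). The 580 odorant receptors measured held 468 higher, 0 lower and 112 that did not pass, with 475 higher and 0 lower adjusted over the list alone (camera adjusted p = 2.92e-15, adjusted p = 0.264 with an estimated correlation). Among 15 sustentacular cell genes, 13 were higher and 0 lower while 2 did not pass, with 13 higher and 0 lower adjusted over the list alone (camera adjusted p = 8.6e-08, adjusted p = 0.144 with an estimated correlation). Of 16 measured G2/M and mitosis genes, 0 were higher, 16 were lower and 0 did not pass, with 0 higher and 16 lower adjusted over the list alone (camera adjusted p = 4.09e-06, adjusted p = 0.349 with an estimated correlation). Aurkb (-4.44) and Cdk1 (-4.36) were lower.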

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

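The tests on mixed cells and on array batch in this part were chosen after the result was seen, as was the block on the noise class. The splits of the arrays were planned.

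The bulbectomy interaction passed for 234 genes, but cannot tell cell population from mouse line, which also differs. Bean1 changed by -0.15 ± 0.38 in Neurog1 cells and 3.12 ± 0.38 in OMP cells (interaction 3.27, adjusted p = 0.00543), Gap43 by 0.33 ± 0.40 and 3.38 ± 0.40 (interaction 3.05, adjusted p = 0.00947), and Slc29a4 by -0.05 ± 0.30 and 3.07 ± 0.30 (interaction 3.12, adjusted p = 0.00233, but 0.03 on its other probe). Slurp2 changed by -0.71 ± 0.49 and 2.50 ± 0.49 (interaction 3.21, adjusted p = 0.0217), and that call ended without any of 7 arrays taken singly: Neurog1-Ctrl 1 and 3, OMP 1, Neurog1-OBX 2 and 3, OMP-OBX 2 and 3 (adjusted p of 0.0572 to 0.0688).

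Other genes differed the other way. Prkd1 changed by 0.73 ± 0.26 and -1.41 ± 0.26 (interaction -2.15, adjusted p = 0.00549). Arhgef25 changed by -0.05 ± 0.37 and -2.32 ± 0.37 (interaction -2.27, adjusted p = 0.0310), and its call ended without Neurog1-Ctrl 1, 2 or 3, Neurog1-OBX 1 or 3, or OMP-OBX 1 or 3 (0.0561 to 0.0851), and on the authors' values, without a detection filter, with the compared groups only or with the mean of all probes (0.05002 to 0.244). Smarcc1 changed by 2.48 ± 0.34 and 0.25 ± 0.34 (interaction -2.23, adjusted p = 0.0220), and the call ended without Neurog1-Ctrl 3, OMP 1, Neurog1-OBX 2 or 3, or OMP-OBX 2 (0.0511 to 0.0680), on the authors' values or with the mean of all probes (0.0654 to 0.107). Fos changed by 2.24 ± 0.39 and 0.11 ± 0.39 (interaction -2.13, adjusted p = 0.0491), and its call ended without Neurog1-Ctrl 1 or 2, OMP 1 or 2, Neurog1-OBX 2 or 3, or any OMP-OBX array (0.0698 to 0.137), and without a detection filter, with the replicate block or with the noise class as a block (0.0671 to 0.0900). Other probes read -0.59 for Smarcc1, 0.22 for Arhgef25, with the opposite sign, and -0.57 and -0.82 for Prkd1.

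Lists with a different lesion effect in the 2 populations by camera were immature olfactory sensory neuron genes (adjusted p = 6.87e-07), odorant receptors (1.94e-07), sustentacular cell genes (5.69e-06), xenobiotic metabolism genes (0.000403), immediate early genes (0.000676), Notch pathway genes (0.0254), apoptosis genes (0.0254) and horizontal basal cell genes (0.0279). None of these 8 passed with an estimated correlation.

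Relabelling the arrays within each population, 6 of 100 drawn splits gave as many interaction genes as the real labels, the real one included, so chance cannot be excluded by this count. The highest other split gave 530 genes, over 2 times the real 234, and it kept the real OMP and OMP-OBX labels. All 5 other splits with as many left the OMP and OMP-OBX labels in place, as 8 of the drawn splits did, and so kept the large OMP effect. The highest split with neither population's labels in place gave 1 gene.

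Immature neuron genes were higher in OMP-OBX than in OMP, with 7 of 19 passing, although the list did not pass with an estimated correlation (adjusted p = 0.217). If cells like the Neurog1-OBX sort as a whole had been carried into the OMP-OBX sort, they would have brought precursor and mitosis genes too. The share of Neurog1-OBX signal needed had a median of 1.35% for 23 precursor and mitosis genes (quartiles -0.685 and 5.33). It was 30.0% for 14 immature genes (quartiles 19.9 and 53.7). The permutation p was 0.00011 with 100000 resamples, but it treats genes as independent replicates, which they are not. The medians argue against a carry-over of that sort as a whole, although Insm1 needed 46.3%, Sox11 17.8% and Prc1 15.2%. Young neurons of that sort carried over alone are not covered by this test. An array batch seen as noise is argued against by the mean shift of 1.10 with the noise class as a block, against 1.18 (adjusted p = 3.52e-08). All OMP-OBX arrays are of 1 noise class, so this rests mainly on the other arrays of that class, OMP 3 and Neurog1-OBX 3. OMP 3 had a list mean of 9.62, between OMP 1 and 2 (9.40 and 9.87) and below every OMP-OBX array (10.69 to 10.90), and Neurog1-OBX 3 read 11.86 against 11.83 and 11.69. A larger share of young neurons that already carry the Omp reporter after the lesion may be the source, as a hypothesis that was not tested.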

How the results depend on the processing

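The block on the noise class and the fit without low-noise arrays were chosen after the spread of the negative controls was seen, and the other settings were planned.

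With array weights 4190 genes were called between Neurog1-Ctrl and Sox2GBC (2019 without weights), 591 between Neurog1-OBX and Neurog1-Ctrl (45), 6696 between Neurog1-Ctrl and OM (4362) and 793 in the interaction (234). With only the compared groups in the fit the counts were 182 for Neurog1-OBX against Neurog1-Ctrl, 980 for OMP against OM (2431; higher calls 128 against 892) and 371 for the interaction. For Neurog1-OBX against Neurog1-Ctrl the noise class as a block gave 94 and the fit without low-noise arrays 145. The correlation of bulbectomy effects was 0.399 with the noise class as a block, against 0.245. Of 286 list tests, 16 passed with an estimated correlation, against 150. For each of these the cause was not tested.

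Without 1 array the counts ran from 1165 to 1680 for Neurog1-Ctrl against Sox2GBC, 8 to 28 for Neurog1-OBX against Neurog1-Ctrl, 651 to 977 for OMP-OBX against OMP, 1435 to 2347 for OMP against OM, 104 to 276 for the interaction and 70 to 147 for genes highest in Neurog1-Ctrl, and the correlation from 0.148 to 0.296 (Spearman 0.018 to 0.162). The cause was not tested.

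The replicate block gave 2380 genes for OM and OMP, and for them changed no call of a named gene or list. These were the only compared groups of the mucosa with every correlation over 0.1. That their numbers pair the samples was not shown. Replicate 1 of both lies in the lowest noise class, and only 1 OM array correlated best with the OMP array of its own number. In other comparisons the replicate block gave 2085 genes for Neurog1-Ctrl against Sox2GBC, 33 for Neurog1-OBX against Neurog1-Ctrl, 1014 for OMP-OBX against OMP and 226 for the interaction, with no count moved by over 1.5 times. OMP and OMP-OBX correlated at 0.09, 0.10 and 0.19, each array best with its own number. A block on the array slide was not run, because slide positions are not given in the sources used here.

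Over all settings but single arrays left out, 155 counts and correlations stayed within their bounds and the 11 given above moved. For list tests 961 kept their side of the threshold, 88 were weaker and 1 stronger, and for named genes 5193, 76 and 95. The apoptosis list in OMP-OBX against OMP had an adjusted p of 0.0951 with the compared groups only, 0.212 with the mean of probes and 0.0184 without a filter, the lowest and highest of its settings apart from the list tests of another kind. Under these settings no called named gene and no list past its threshold changed direction.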

Other observations

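All tests on mouse lines, probes and the Chil genes in this part were chosen after the result was seen, while the splits of the arrays were planned.

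Immediate early genes, 13 in the list, had mean log2 signals of 12.3 ± 0.20 SD in Sus, 10.6 ± 0.44 in OM, 9.52 ± 0.18 in Sox2GBC, 8.04 ± 0.23 in Neurog1-Ctrl and 8.84 ± 0.44 in OMP, and of 9.23 ± 0.32 in Neurog1-OBX and 9.10 ± 0.11 in OMP-OBX. Mitosis genes, 16 in the list, averaged 9.28 in Sus with an SD of 1.27 between its 3 arrays, against 8.49 ± 0.29 in Neurog1-Ctrl and 6.51 ± 0.14 in OMP. Avp averaged 6.53 before and 9.84 after the lesion in Neurog1 cells and 7.79 and 11.1 in OMP cells. Ang4 averaged 7.62 and 11.3 in Neurog1 cells, which did not pass (adjusted p = 0.0502), and 5.19 and 9.93 in OMP cells. Obp2a, a secreted odorant binding protein gene, varied within groups with SD of 1.34 to 3.73. Xist was detected on 0 of 3 arrays of Neurog1-OBX, on 3 of 3 in OMP-OBX, Sus and mREF, and on 2 of 3 in the other groups. On their brightest probes the Y-linked genes Eif2s3y and Kdm5d were detected on 0 and 2 arrays of Neurog1-Ctrl, 1 and 2 of Neurog1-OBX, 1 and 1 of OMP and 3 and 2 of OMP-OBX. A dimmer Eif2s3y probe was also detected on Neurog1-OBX 3. Xist together with a Y-linked gene was detected on 0 of 3 OMP arrays and 3 of 3 OMP-OBX arrays. Detection of sex-linked genes is thus not balanced over the lesion in either population or in the interaction. The sex of the pooled mice is not given in the sources used here.

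Genes low on every array of 1 mouse line, by at least 1 log2 unit, numbered 33: 6 for the Sox2-GFP line (Sox2GBC and Sus), 9 for the Neurog1-GFP line (among them Cfap69, Tesk1, Fgfr1op2 and Tomm22) and 18 for the OMP-GFP line (among them Cdk1, Grp, Hes6 and Mcm2), against 0 in all 18 pairs of groups from different lines. Genes high on every array of a pair did not follow the lines: 6 for OM with Sus and 3 for OM with OMP, against 1, 1 and 0 for the pairs of 1 line. Of the named largest changes 5 are among the 33 low genes. A strain variant under the probe stays open. Genes were picked on the used probe, so a smaller gap on others cannot decide it. Median shares of the used probe's gap were 0.278 for Neurog1-GFP (5 probes, quartiles 0.250 and 0.341, Cfap69 0.741). They were 0.585 for Sox2-GFP (7 probes, quartiles 0.341 and 0.741) and 0.84 for OMP-GFP (11 probes, quartiles 0.362 and 0.954). Sox2-GFP mice, also crossed to FVB/NJ, lacked the Neurog1-GFP gap. A line difference stays open too, as line and cell stage are confounded: of the 6 genes low in Sox2GBC and Sus, 0 were not higher in OMP than in OM. Both tests were first run over all lines (median 0.585, and 6 genes against 0) and divided by line and restricted after those values were seen.

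Chil3 and Chil4 were higher after bulbectomy in both sorted populations. For Chil4 the lowest bulbectomy array lay 0.85 log2 units above the highest array of any other group of the mucosa, a Sus array (SD in Sus 0.78), which argues, by a narrow margin, against unlesioned cells of another population here mixed into the sorts. For Chil3 the same value was -0.31, which leaves this open. The test was first made on the smaller value of both genes and was divided by gene after it was seen. Leukocytes recruited after the lesion stay open. The leukocyte list passed by camera in Neurog1 cells but not in OMP cells, and the smaller median rise was 0.06. Cd74 read 7.56 before and 8.93 after in Neurog1 cells, 8.06 and 8.64 in OMP cells and 12.3 in OM. A response of the sorted cells or of their neighbours may also be the source.

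For each comparison of 3 arrays with 3 the 10 splits are too few for a share under 0.05, and 1 split, the real one, gave as many genes. The real count and the highest other were 2019 and 0 for Neurog1-Ctrl against Sox2GBC, 4279 and 0 for OMP against Neurog1-Ctrl, 6167 and 21 for Sus against Sox2GBC, 45 and 1 for Neurog1-OBX against Neurog1-Ctrl and 1028 and 0 for OMP-OBX against OMP. Against OM they were 3896 and 3 for Sox2GBC, 4362 and 0 for Neurog1-Ctrl, 2431 and 157 for OMP and 5759 and 685 for Sus, and 8277 and 90 for OM against mREF. The splits with 157, 685 and 90 genes put the arrays of the lower noise classes on 1 side. If replicate numbers paired the OM and OMP samples, which was not shown, 4 splits part as many pairs, and the highest of the others among them gave 2 genes. For genes highest in Neurog1-Ctrl, 1 of 100 drawn splits, the real one, gave as many (159, highest other 53). Other splits also remove the differences at each single step, so this says nothing on a peak in that group, and 159 is below the 171.6 of independent lists.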
